A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

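Haploid MATa yeast of 2 strains, crz1 and crz1cnb1, were sampled at 0 h and after 48 h in 400 mM KCl, with 3 replicates per group and 12 libraries in all. The series describes triplicate experiments. Poly(A) RNA was sequenced. The authors deposited a table of counts per gene (7126 genes and other features) and a table of TPM, transcripts per 1000000 (6735 features), with 1 column per library, per the file headers. The submitters' processing notes name featureCounts and DESeq2, with no version or role, and the genome build R64. The aligner, the annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Values of overlapping genes, of antisense partners and of near-identical copies are therefore uncertain.

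Each table was checked for its unit. Counts were whole numbers that summed to 21305485 to 21599279 per library, and counts over TPM stood in a fixed ratio between libraries for every gene. Of the count features, 207 were 0 in all 12 libraries, 2016 had no standard name, and 391 were not in the TPM table, of which 207 were at 0. Gene positions and overlaps came from a reference table of the same build, in which 6048 of the 7126 identifiers matched. The share of each gene's 50-mers found elsewhere in the genome was computed as a mark of shared reads. The 10 most abundant genes took 10.7 to 16.6% of a library, ribosomal protein genes 17.8 to 21.6%, and the 28 features of the mitochondrial genome 0 or 1 count per library (5 in total), so they were not tested. Library pairs within a group differed by 78.0 to 249.6 times the counting noise (chi-squared per degree of freedom), so no library was a copy of another.

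The test was edgeR 4.0.16 (R 4.3.3) on the deposited counts. It used TMM scaling (factors 0.791 to 1.17), filterByExpr by group, 1 coefficient per group, robust glmQLFit and glmQLFTest over all 12 libraries, and Benjamini-Hochberg adjustment at 0.05. It tested 6309 features, 4976 of them with a standard name, which held at least 99.99% of each library, and the common biological coefficient of variation was 0.223. Comparisons were KCl against 0 h in each strain, the difference between those responses, and crz1 minus crz1cnb1 at 0 h and in KCl. CPM values are TMM-scaled, errors of log2 fold changes are standard errors, and intervals are 95% by the normal distribution. Such intervals are narrower than the quasi-likelihood test, with its few degrees of freedom, would give. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with an estimated one, where at least 3 members were tested. List members were also adjusted over the list alone. Correlations and overlaps of the responses were described across genes without a p-value.

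Replicate numbers were checked for pairing. Deviations from the group means correlated at 0.309 to 0.827 in the 18 pairs of libraries with the same number, and at -0.732 to 0.317 in the 36 pairs with different numbers. Every same-number correlation was over 0.1, so the numbers pair the samples. The main test was fixed before the data were examined and has no block. Its errors include the differences between replicate numbers, and it called fewer KCl responses and strain differences than the fits with a block. The pairing comes from these correlations, since the labels name no shared day or batch.

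The alternatives fixed before the data were examined were DESeq2 size factors, library totals without a factor, no filter, DESeq2 1.42.0, limma voom, limma trend on log2(TPM + 1) and on log2(TPM + 0.1), glmTreat at a fold of 1.5, the replicate number as a block and as a block nested in strain, the 6 libraries compared alone, leaving out each of the 12 libraries, fry and an estimated correlation for lists, and a minimum of 32 CPM for the correlation. Added after the data were seen were the block nested in treatment, all 4 libraries numbered 2 left out, DESeq2 with the block, other scalings and left-out libraries for the lists, the overlap with the block or with libraries left out, correlations of single pairs, and the strain difference averaged over both treatments.

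The code was tested on simulated counts with 50 changed genes per fold size among 6309. The counts were drawn from a model with blocks of treatment and replicate number and a strain effect, the structure of the block nested in treatment. Changed genes were drawn only from those above a minimum mean expression. The recovery therefore favours the nested block and does not cover genes of low expression. For the difference between responses it recovered 0, 1, 44 and 50 of 50 at 1.5-, 2-, 4- and 8-fold, with 0 unchanged genes called. With the replicate block it recovered 6, 33, 49 and 50, and with the block nested in treatment 32, 49, 50 and 50, with 7 unchanged genes called. For the strain difference in KCl it recovered 1, 23, 50 and 50, and with the block nested in treatment 45, 50, 50 and 50.

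Named genes, the lists and the comparisons were fixed at the same time as these alternatives. Named genes followed a rule. For each comparison the rule took up to 12 genes per direction with the largest change among called genes that had a standard name, a mean above 10 CPM in a group compared, and groups that do not overlap. It added all genes of the lists of strain markers, Crz1 targets, glutathione and genes beside the deletions, and up to 4 members of each other list by adjusted p. In crz1, 13 higher and 9 lower genes met the first part, in crz1cnb1 17 and 7, and 0 in the strain comparisons. A gene named for 1 comparison is also given in others. Genes named outside the rule are said to have been chosen after their values were seen.

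The lists were strain markers, Crz1 targets, glutathione, sulfate and methionine, redox defence, osmotic stress, general stress, heat shock, unfolded protein response, ribosomal proteins, ribosome biogenesis, respiratory chain, mitochondrial genome, tricarboxylic acid cycle, glycolysis, hexose transport, cell wall, cation transport, calcium signalling, phosphate starvation, iron, zinc and copper, nitrogen, Gcn4-controlled amino acid synthesis, ergosterol, pheromone, G1/S, histones, Hcm1 targets, G2/M, M/G1, opposite mating type, meiosis, stationary phase and neighbours of the deleted genes. Strain markers, the mitochondrial genome and neighbours were not set-tested. Added later were other Pdr1 and Pdr3 targets, and anaerobic and heme-repressed genes, without the members already seen to rise, with camera p-values adjusted over these 4 tests. List members too low to be tested were CRZ1, URA3, LYS2, ENA2, HXT13, HXT14, HXT16, CUP1-1, CUP1-2, DAL80, SPS2, SPG1 and the 8 mitochondrial genes, and HPH1 was not found under that name. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.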

Results

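Poly(A) RNA was measured by sequencing in 12 samples of haploid budding yeast in the BY4741 background, 3 replicates in each of 4 groups. Both strains lacked CRZ1, which encodes the transcription factor that the phosphatase calcineurin activates. The strain called crz1cnb1 also lacked CNB1, which encodes the regulatory subunit of calcineurin. Each strain was sampled before treatment (0 h) and after 48 h in 400 mM KCl, with dilution every 12 h to keep the cells in logarithmic growth. No untreated cells were sampled at 48 h. The changes called KCl responses below therefore cannot be told apart from changes due to 48 h of culture alone. The deposited counts summed to 21305485 to 21599279 per library, and 3 counts, the limit that a count of 0 allows, stood for 0.139 to 0.141 CPM (counts per 1000000). Such floors cover counting error only. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. The first principal component held 33.7% of the variance and separated KCl from control libraries, except that the KCl libraries numbered 2, at -6.55 (crz1) and -4.53 (crz1cnb1), lay on the side of the controls.

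**Figure D1:**
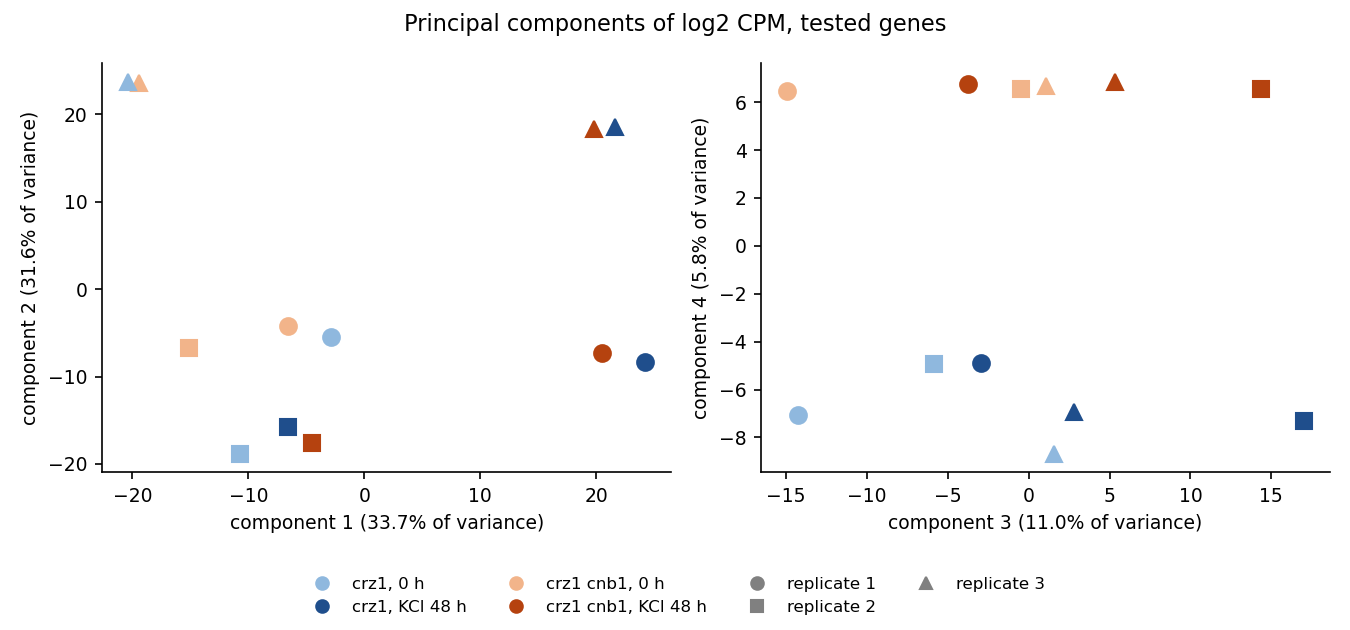
Principal components of log2 CPM over the tested genes, with each point a library, colours for the 4 groups and shapes for the replicate numbers. Component 1 held 33.7% of the variance, component 2, which followed the replicate numbers, 31.6%, and component 4, which followed the strain, 5.83%.

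The deleted genes were examined in every library as a check of the labels. CNB1 (YKL190W, chromosome XI, 82947 to 83550, build R64) had 14 to 31 counts per library in crz1cnb1 at 0 h and 31 to 68 in KCl. In crz1 it had 1346 to 2889 counts at 0 h and 2416 to 3139 in KCl. CNB1 was therefore higher in crz1 by a log2 difference of 6.61 ± 0.34 at 0 h (SE; 95% interval 5.93 to 7.28; edgeR adjusted p = 4.03e-07; higher in 3 of 3 pairs), from means of 105 ± 27.0 and 1.06 ± 0.36 CPM (SD, n = 3). CRZ1 had 3 to 19 counts in all 12 libraries, too few to be tested. URA3 and LYS2, which the genotype lists as deleted in both strains, had 0 counts in every library. LEU2, the marker that replaced CRZ1, had 6973 to 12312 counts, and HIS3, which the genotype lists as mutated, had 505 to 1943. MET17 (also called MET15), which BY4741 lacks but the genotype does not list as deleted, had 8255 to 27137 counts in all 12 libraries. The counts of LYS2 and MET17 thus follow the listed genotype, and they do not show that the background is BY4741. The catalytic subunits of calcineurin did not differ between strains by this test at 0 h, with log2 differences of -0.10 ± 0.19 for CNA1 and -0.14 ± 0.16 for CMP2. Among the 4 genes beside the deletions (SAM50, KTR5, DPH2 and HYM1), 0 were called in edgeR in either strain comparison.

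The comparison of KCl with 0 h in crz1 asked which genes differed after 48 h in KCl when Crz1 was absent. The largest rise among the named genes was that of RSB1 (YOR049C, chromosome XV, 422668 to 423732), which encodes a membrane protein that moves sphingoid bases. RSB1 went from 4.22 ± 0.47 to 56.0 ± 16.1 CPM (SD, n = 3), a log2 fold change of 3.73 ± 0.31 (SE; 95% interval 3.13 to 4.33; edgeR adjusted p = 5.65e-05). HSP12 (YFL014W, chromosome VI, 107256 to 107585), a membrane-stabilising stress protein, rose by 2.92 ± 0.27 on the log2 scale (adjusted p = 1.39e-04), from 43.5 ± 7.71 to 329 ± 61.3 CPM. GPP2 (YER062C, chromosome V, 279930 to 280682), a phosphatase of glycerol synthesis, rose by 1.74 ± 0.21 (adjusted p = 0.00145), from 175 ± 29.8 to 584 ± 32.1 CPM. The drug efflux pump gene PDR5 rose by 1.10 ± 0.18, its regulator PDR3 by 1.06 ± 0.17, the reductase gene GRE2 by 1.30 ± 0.19 and the phosphatase gene PHM8 by 2.03 ± 0.30. DAN1, a cell wall mannoprotein gene of anaerobic cells, rose by 3.55 ± 0.30 from 0.745 ± 0.22 CPM. Lower in KCl were STE3 (YKL178C, chromosome XI, 113215 to 114627), the a-factor receptor gene, at -3.08 ± 0.25 (adjusted p = 5.65e-05), and MMP1 (YLL061W, chromosome XII, 17956 to 19707), an S-methylmethionine permease gene, at -1.76 ± 0.18 (adjusted p = 2.26e-04). MET3 (YJR010W, chromosome X, 456239 to 457774), which encodes ATP sulfurylase, had -1.30 ± 0.17, the glucose transporter gene HXT4 -2.30 ± 0.41, and the putative permease gene SEO1 -1.78 ± 0.24.

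In crz1, edgeR's quasi-likelihood test called 36 of 6309 tested genes, 22 higher and 14 lower in KCl, and 32 of them changed at least 2-fold. In all 36 genes the 3 KCl libraries lay entirely above or below the 3 controls, which held for 10.3% of all tested genes, where chance gives 10%. With the replicate number as a block the count was 304 (214 higher, 90 lower), all 36 among them, and DESeq2 called 107. The count was 12 without crz1 KCl replicate 1 and 60 without KCl replicate 2, and 19, 16 and 16 without crz1 control replicates 1, 2 and 3. The calls of RSB1, HSP12, PHM8, GPP2, GRE2, DAN1, STE3, MMP1, MET3 and SEO1 held in all 12 fits that left out 1 library. Those of PDR5, PDR3 and HXT4 held in 7, 8 and 9 of the 12. All 3 ended without crz1 KCl replicate 1 or without crz1 control replicate 1. PDR5 and HXT4 also lost theirs without control replicate 3, and PDR5 and PDR3 lost theirs without control replicate 2 or KCl replicate 3. Across the 26 alternatives the adjusted p ranged from 1.43e-22 to 0.302 for PDR5, from 5.43e-17 to 0.355 for PDR3 and from 7.54e-21 to 0.132 for HXT4.

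The same comparison in crz1cnb1 asked which genes changed when calcineurin was absent as well. RSB1 rose by 3.33 ± 0.30 on the log2 scale (SE; 95% interval 2.74 to 3.92; edgeR adjusted p = 2.50e-04), from 5.12 ± 1.37 to 51.4 ± 15.6 CPM (SD, n = 3). HSP12 rose by 2.39 ± 0.27 (adjusted p = 8.62e-04), GPP2 by 1.53 ± 0.21 (adjusted p = 0.00498) and DAN1 by 3.45 ± 0.34 (adjusted p = 2.80e-04). Genes of iron acquisition were among the largest rises: the cell wall siderophore-binding protein gene FIT3 (YOR383C, chromosome XV, 1060441 to 1061055) by 3.41 ± 0.67 (adjusted p = 0.0421), the heme oxygenase gene HMX1 by 2.41 ± 0.39, and the reductase gene FRE5 by 2.75 ± 0.51. FIT3 varied widely in KCl, at 1815 ± 1354 CPM against 171 ± 115 at 0 h. The omega-class glutathione transferase gene GTO3 rose by 2.09 ± 0.34 (adjusted p = 0.0133). MMP1 fell by 1.90 ± 0.18 (adjusted p = 2.50e-04), STE3 by 2.69 ± 0.26 (adjusted p = 2.80e-04), MET3 by 1.28 ± 0.17 (adjusted p = 0.00406), HXT4 by 2.45 ± 0.40 and the sulfite reductase gene MET5 by 1.33 ± 0.21.

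In crz1cnb1, edgeR called 37 genes, 23 higher and 14 lower in KCl, and 34 changed at least 2-fold. All 37 separated the KCl libraries from the controls, as did 13.3% of all tested genes, where chance gives 10%. With the replicate block the count was 314 (169 higher, 145 lower), all 37 among them, and DESeq2 called 120. It was 14, 12 and 9 without crz1cnb1 control replicates 1, 2 and 3, and 18 and 19 without KCl replicates 1 and 3. RSB1, HSP12, GPP2, DAN1, STE3, MMP1 and MET3 kept their calls in all 12 fits that left out 1 library. HMX1, GTO3 and MET5 lost theirs without crz1cnb1 control replicates 2 or 3, HXT4 without control replicates 1 or 3 or KCl replicate 1, and FRE5 without any of the 3 controls or without KCl replicates 1 or 3. GRE2 lost its call without control replicates 1 or 3 or KCl replicates 1 or 3, and PHM8 without any of the 3 controls or without KCl replicates 1 or 3. FIT3 was called in 4 of the 12 fits and was lost without any crz1 or crz1cnb1 control, crz1cnb1 KCl replicate 3 or crz1 KCl replicate 1 (adjusted p of 1.07e-09 to 0.228 over the 26 alternatives).

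**Figure D2:**
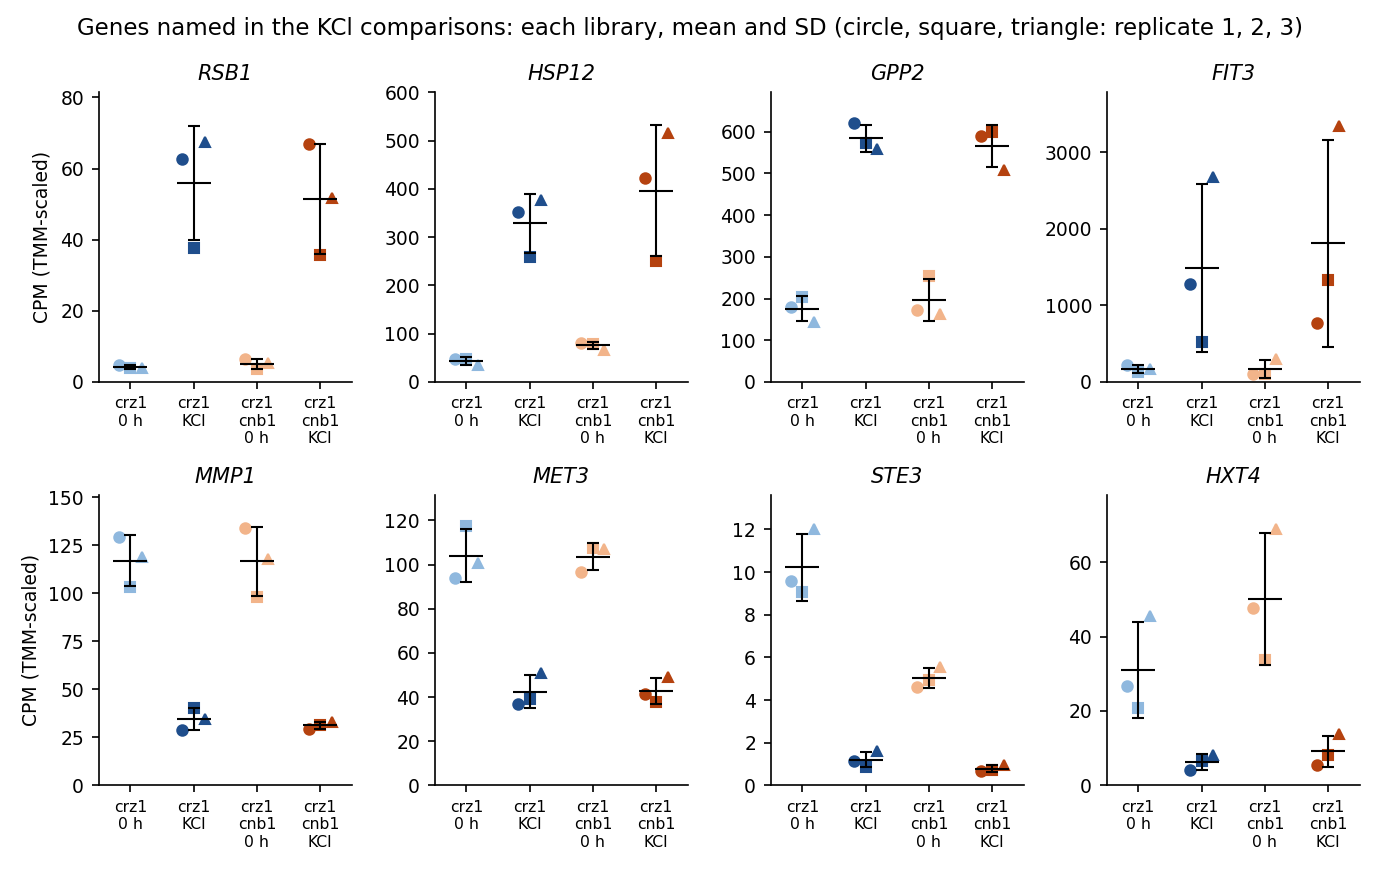
TMM-scaled CPM of 8 genes named in the KCl comparisons in each library (points; circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of the 3 replicates, for both strains at 0 h and after 48 h in KCl. RSB1 went from 4.22 to 56.0 CPM in crz1 and from 5.12 to 51.4 CPM in crz1cnb1.

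Among the gene lists, genes of sulfate assimilation and methionine were lower in KCl in both strains. Their 26 members had median log2 fold changes of -0.37 in crz1 and -0.36 in crz1cnb1, and 21 were negative in each strain (camera adjusted p = 5.88e-11 and 1.65e-10). In each strain 0 members rose and 5 fell over all genes. Adjusted over the list alone, 10 fell in each and 1 rose in crz1. With the replicate block over all genes, 10 fell in each strain and 0 rose. MMP1, MET3 and MET5 were among the 5 in both strains, as was MET17 (-1.12 ± 0.23 and -1.26 ± 0.23), a sulfhydrylase gene that overlaps YLR302C. The calls of MET5 and MET17 in crz1 ended without crz1 control replicates 2 or 3 or KCl replicates 1 or 2, and that of MET17 also without crz1 control replicate 1, any crz1cnb1 control or crz1cnb1 KCl replicate 1. In crz1cnb1 that of MET5 ended without crz1cnb1 control replicates 2 or 3, and that of MET17 without any crz1cnb1 control or without crz1cnb1 KCl replicates 1 or 2. This was the only list of the 32 tested in each KCl response whose camera call held with an estimated correlation (adjusted p = 0.0017 and 0.00211), but with the replicate block that adjusted p was 0.0513 and 0.0662.

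Iron regulon genes were higher in KCl, with 21 of 22 positive in each strain and medians of 1.16 in crz1 and 1.37 in crz1cnb1 (camera adjusted p = 8.61e-13 and 9.17e-17; adjusted p = 0.314 and 0.185 with an estimated correlation). Over all genes 1 member rose in crz1 and 5 in crz1cnb1. When adjusted over the list alone, 12 and 13 did, and with the block over all genes 10 and 14. The mRNA decay factor gene TIS11 rose in both strains, by 1.51 ± 0.26 and 1.60 ± 0.26. Its call ended in crz1 without control replicates 2 or 3 or KCl replicate 1, and in crz1cnb1 without control replicate 3. FIT3 had 3.12 ± 0.67 in crz1 (adjusted p = 0.065; 0.00633 with the block), and its responses differed between strains by -0.29 ± 0.87 (interaction adjusted p = 1). The corresponding differences were -0.66 ± 0.68 for FRE5, -0.65 ± 0.52 for HMX1 and -0.48 ± 0.46 for GTO3. Pair by pair, the list's median was 0.79, 0.77 and 1.45 in crz1.

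Osmotic stress genes were also higher, with 18 of 20 positive in crz1 and 19 in crz1cnb1, and medians of 0.66 and 0.61 (camera adjusted p = 8.83e-11 and 4.06e-10; adjusted p = 0.204 and 0.185 with an estimated correlation). HSP12, GPP2 and GRE2 rose in both strains over all genes, and adjusted over the list alone 8 and 9 members did. With the replicate block 8 members rose in each strain. GPD1, the dehydrogenase gene of glycerol synthesis, had 1.14 ± 0.36 and 1.18 ± 0.36 and was called only with the block (adjusted p = 0.00405 and 0.00334). General stress genes had medians of 1.02 and 1.06, with 23 and 25 of 26 positive (camera adjusted p = 2.65e-09 and 2.85e-08; adjusted p = 0.46 and 0.413 with an estimated correlation). HSP12 was the 1 member that rose over all genes, and 12 and 5 adjusted over the list alone. With the replicate block 5 general stress genes rose in crz1 and 3 in crz1cnb1. In the pair numbered 2 the median of the general stress genes was -0.17 in crz1 and -0.26 in crz1cnb1, against 1.24 and 1.55, and 0.92 and 1.61, in the other pairs. Genes high in stationary phase had medians of 0.47 and 0.83 (camera adjusted p = 1.47e-04 and 1.97e-06; adjusted p = 0.314 and 0.185 with an estimated correlation), with HSP12 as the member that rose over all genes and 4 and 6 adjusted over the list alone.

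Pheromone and a-cell genes were lower in KCl, with 24 of 26 negative in each strain and medians of -0.49 and -0.56 (camera adjusted p = 2.86e-08 and 2.03e-09; adjusted p = 0.359 and 0.283 with an estimated correlation). Over all genes 0 members passed edgeR's test without a block in either strain. With the replicate block 1 rose and 9 fell in crz1, and 2 rose and 10 fell in crz1cnb1. Adjusted over the list alone, 1 rose and 7 fell in crz1, and 2 rose and 10 fell in crz1cnb1. STE6, the a-factor exporter gene, had -0.55 ± 0.16 in crz1 and -0.54 ± 0.16 in crz1cnb1, called with the block (adjusted p = 0.0105 and 0.012). Of the 4 genes of the opposite mating type, all were negative, and STE3 fell over all genes and adjusted over the list alone (camera adjusted p = 1.26e-05 and 8.52e-04; adjusted p = 0.122 and 0.185 with an estimated correlation). Phosphate starvation genes had medians of -0.19 and -0.37 (camera adjusted p = 8.95e-04 and 1.97e-06; adjusted p = 0.46 and 0.309 with an estimated correlation). Among their 19 members, PHM8 rose in both strains, and 2 fell in crz1 and 3 in crz1cnb1. Of these genes 5 and 6 fell and 1 rose in each strain when adjusted over the list alone. In crz1 the median of the phosphate genes was 0.25 in the pair numbered 2, against -0.21 and -0.48 in the others. SPL2, a regulator of low-affinity phosphate uptake, fell by 2.08 ± 0.30 and 1.44 ± 0.26, a call lost in crz1 without KCl replicate 1, and in crz1cnb1 without any control or without KCl replicates 2 or 3.

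Genes of protein synthesis and respiration were slightly lower. The 132 ribosomal protein genes had medians of -0.13 in crz1 and -0.21 in crz1cnb1, with 114 and 126 negative (camera adjusted p = 4.49e-05 and 7.50e-12; adjusted p = 0.587 and 0.319 with an estimated correlation). Ribosome biogenesis genes had medians of -0.28 and -0.24, with 28 and 29 of 30 negative (camera adjusted p = 6.22e-07 and 4.54e-05; adjusted p = 0.46 and 0.557 with an estimated correlation). In both lists 0 members passed edgeR's test over all genes or adjusted over the list alone. With the replicate block 4 ribosomal protein genes fell in crz1cnb1, and 0 members of either list were called otherwise. In the pair numbered 2 the median of the ribosome biogenesis genes was 0.09 in crz1 and 0.21 in crz1cnb1, against -0.44 and -0.61, and -0.40 and -0.63, in the other pairs. That of the ribosomal protein genes in crz1 was 0.15, against -0.39 and -0.11. RPA190, the largest subunit gene of RNA polymerase I, had -0.72 ± 0.24 in crz1. Respiratory chain genes had medians of -0.22 and -0.33 (camera adjusted p = 8.95e-04 and 2.41e-09; adjusted p = 0.587 and 0.309 with an estimated correlation). None fell over all genes without a block, and 10 in crz1cnb1 adjusted over the list alone. With the replicate block 2 fell in crz1 and 11 in crz1cnb1, and 0 rose. CYC1, a cytochrome c gene, had -1.56 ± 0.42 and -1.64 ± 0.42 and was called with the block (adjusted p = 0.00249 and 0.00253). Of 14 hexose transporter genes tested, HXT4 fell in both strains, and adjusted over the list alone 3 fell in each and 1 rose in crz1cnb1 (camera adjusted p = 0.00425 and 0.0264; adjusted p = 0.46 and 0.488 with an estimated correlation). With the block the call in crz1cnb1 was lost (adjusted p = 0.076).

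Cell cycle and biosynthesis lists moved little. Genes of the M/G1 wave had medians of -0.18 and -0.14 (camera adjusted p = 0.011 and 0.00363; adjusted p = 0.46 and 0.41 with an estimated correlation), with 0 called over all genes and 1 lower in each strain adjusted over the list alone. With the replicate block 1 M/G1 gene fell in crz1 and 3 in crz1cnb1. Amino acid synthesis genes under Gcn4 had medians of -0.14 in both strains (camera adjusted p = 0.011 and 9.79e-04; adjusted p = 0.739 and 0.673 with an estimated correlation), and one of 0.15 in the crz1 pair numbered 2. G2/M genes had a median of 0.15 in each strain (camera adjusted p = 0.0374 in crz1 and 0.0826 in crz1cnb1; adjusted p = 0.46 with an estimated correlation in crz1). Ergosterol synthesis genes had medians of -0.02 and -0.17 (camera adjusted p = 0.317 in crz1 and 0.00613 in crz1cnb1; adjusted p = 0.582 with an estimated correlation in crz1cnb1). Neither of these lists was called in the interaction (camera adjusted p = 0.847 and 0.0615), and in these 3 lists 0 members passed edgeR's test over all genes or adjusted over the list alone. With the replicate block 1 amino acid gene fell in crz1, and in crz1cnb1 1 G2/M gene rose and 1 ergosterol gene fell.

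Lists whose camera test passed in neither KCl response were those of glutathione metabolism, redox defence, heat shock chaperones, the unfolded protein response, the tricarboxylic acid cycle, glycolysis, the cell wall, cation transport, calcium signalling, zinc and copper, nitrogen, the G1/S wave, histones, Hcm1 targets and meiosis. Their adjusted p was at least 0.169. Heat shock genes had medians of -0.52 in crz1 and -0.43 in crz1cnb1 in the pair numbered 2, against 0.16 and 0.41, and 0.33 and 0.36, in the other pairs. Members that rose over all genes were GRE2 of the redox list in both strains, the malate synthase gene MLS1 of the tricarboxylic acid cycle in crz1 (1.67 ± 0.28; interaction 0.43 ± 0.39), and DAN1 of the cell wall list in both. Adjusted over the list alone, 1 to 3 members of these 3 lists rose. In the redox list 1 fell in each strain, and 1 meiosis gene rose in crz1, when adjusted over the list alone. MLS1 lost its call without crz1 control replicates 1 or 3 or KCl replicate 1. Of the 22 glutathione genes 0 passed edgeR's test over all genes in either strain, and 1 fell in crz1 adjusted over the list alone. With the block 2 were called in crz1 and 4 in crz1cnb1. GTT1, a glutathione transferase gene, had 0.82 ± 0.37 in crz1 (adjusted p = 0.00944 with the block), and OPT1, a glutathione transporter gene, -0.68 ± 0.18 (adjusted p = 0.00258 with the block). Median, mean and test differed in sign for glutathione, heat shock, glycolysis, cell wall and zinc and copper in crz1. They did so for the unfolded protein response, glycolysis, cell wall, cation transport and G1/S in crz1cnb1. They also did so for sulfate and methionine, Hcm1 targets, G2/M and meiosis in the difference between the responses, and for sulfate and methionine and ribosome biogenesis between strains at 0 h. In KCl the lists between strains were redox defence, general stress, unfolded protein response, zinc and copper, amino acid synthesis and histones. None of these lists was called where the signs differed.

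Known targets of Crz1 were examined because both strains lacked it. Of 15 tested targets, 0 passed edgeR's test in either KCl response, over all genes or adjusted over the list alone, and 0 with the block (camera adjusted p = 0.811 in crz1 and 0.355 in crz1cnb1). ENA1, a sodium pump gene, had 0.13 ± 0.28 in both strains (95% interval in crz1 -0.41 to 0.67), with 88.5% of its 50-mers shared with other genes. PMC1, a vacuolar calcium pump gene, had 0.28 ± 0.27 and 0.26 ± 0.27 (95% interval in crz1 -0.25 to 0.82). RCN1, a calcineurin regulator gene, had 0.29 ± 0.23 and 0.21 ± 0.23, and CMK2, a calmodulin kinase gene, 0.19 ± 0.16 and 0.11 ± 0.16.

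The difference between the 2 responses, crz1 minus crz1cnb1, asked which KCl changes needed calcineurin when Crz1 was absent. No gene was shown to respond differently: edgeR called 0 of 6309, DESeq2 0, and the replicate block 0, with 18 genes at an unadjusted p under 0.05 in edgeR and 15 in DESeq2. That number was 68 with the replicate block and 276 with the block nested in treatment. In edgeR the 18 genes were 0.285% of those tested, where a share near 0.05 would arise without any difference. Errors of the test without a block include the differences between replicate numbers, so it was too cautious. Its 0 calls do not by themselves show that the responses were equal. RSB1 differed by 0.40 ± 0.40, GPP2 by 0.21 ± 0.29, MMP1 by 0.14 ± 0.24, MET3 by -0.02 ± 0.24 and HXT4 by 0.15 ± 0.55. HSP12 differed by 0.53 ± 0.36 (95% interval -0.18 to 1.24), ENA1 by 0.00 ± 0.39 and PMC1 by 0.02 ± 0.39. STL1, a glycerol importer gene, differed by -1.05 ± 0.49 (95% interval -2 to -0.10, adjusted p = 1). Of 5089 genes above 10 CPM, 4354 (85.6%) had 95% intervals within 2-fold in either direction, and 5065 (99.5%) with the block nested in treatment, which also called 0 genes. The intervals come from the normal distribution and are narrower than the test's own. Both shares are therefore upper values, and the interval of STL1 is too short. On simulated counts for this comparison the test without a block recovered 1 of 50 genes at 2-fold and 44 of 50 at 4-fold. At 2-fold the replicate block recovered 33, and the block nested in treatment 49, with 7 unchanged genes called. The simulation had the structure of the nested block and left genes of low expression unchanged, so these numbers do not give the recovery in the real data.

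Gene lists differed little between the responses. Ribosomal protein genes had a median difference of 0.10, with 109 of 132 positive, and respiratory chain genes one of 0.15, with 34 of 38 positive (camera adjusted p = 1.36e-04 for each; adjusted p = 0.919 for each with an estimated correlation). Iron genes had a median of -0.21, with 20 of 22 negative (camera adjusted p = 0.0229, and 0.919 with an estimated correlation). Of the 12 fits that left out 1 library, 10 kept the call of ribosomal protein genes, 7 that of respiratory chain genes and 7 that of iron genes. In these 3 lists 0 members passed edgeR's test over all genes or adjusted over the list alone. With the replicate block ergosterol genes were also called (median 0.14; adjusted p = 0.00398). Without the 4 libraries numbered 2 none of the 3 was called, and the direction for ribosomal protein and respiratory chain genes turned. That fit called 2 other lists, pheromone genes (adjusted p = 0.0274) and stationary phase genes (adjusted p = 0.0125), both lower, and for pheromone genes this was opposite to the direction in all libraries.

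The KCl responses of the strains, which share no libraries but share replicate numbers, were compared across the 6309 tested genes. Deviations of libraries with the same number and treatment correlated between the strains at 0.542 to 0.827. The responses of the strains are therefore not independent, and shared deviations can raise the overlap and the correlation given here. RSB1, HSP12, GPP2, GRE2 and DAN1 were among 17 genes that rose in both, and STE3, MMP1, MET3 and HXT4 among 11 that fell in both, where independent lists would share 0.0802 and 0.0311. With the replicate block 118 and 67 were shared. All 36 genes called in crz1 had the same direction in crz1cnb1, with a median ratio of log2 fold changes of 0.886, and all 37 called in crz1cnb1 had the same direction in crz1, with a median ratio of 0.988. Across genes, which are not independent replicates, Pearson's r was 0.813 and Spearman's rho 0.719. For single pairs of libraries r averaged 0.643 (matched numbers) and 0.388 (different numbers). Leaving out 1 library moved the 28 shared calls by more than 1.5 times in 9 of 12 fits: 17, 14 and 15 without crz1 controls 1, 2 and 3, 12 without crz1 KCl replicate 1, 11, 11 and 9 without crz1cnb1 controls 1, 2 and 3, and 15 and 16 without crz1cnb1 KCl replicates 1 and 3.

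**Figure D3:**
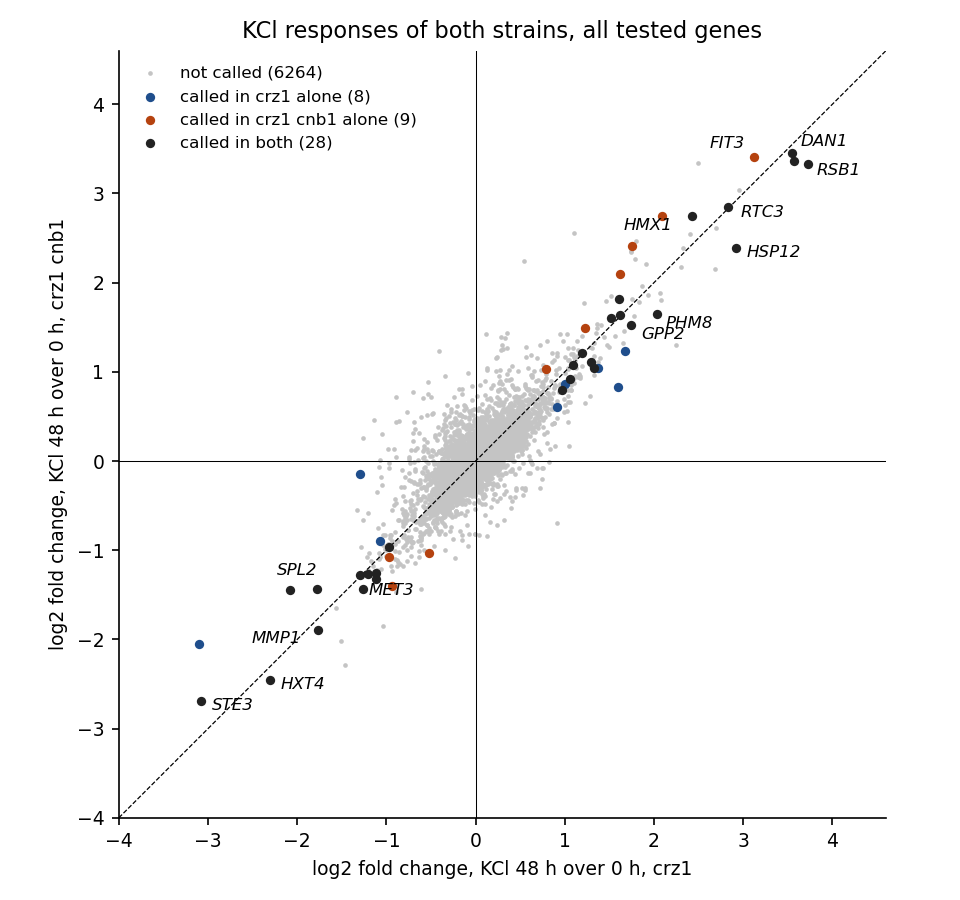
Log2 fold change after 48 h in KCl in crz1 (horizontal axis) and crz1cnb1 (vertical axis), with each point 1 of 6309 tested genes and colours for genes called in edgeR. The 28 genes called in both strains had the same direction in both.

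The strain comparison at 0 h, crz1 minus crz1cnb1, asked what loss of calcineurin changed before KCl. Phosphate starvation genes were lower in crz1, with 16 of 19 negative and a median of -0.34 (camera adjusted p = 6.40e-18; adjusted p = 0.179 with an estimated correlation). None passed edgeR's test over all genes, with 4 lower adjusted over the list alone, 2 over all genes with the replicate block and 6 with the block nested in treatment. PHO89 (YBR296C, chromosome II, 796798 to 798522), a phosphate transporter gene, had -1.64 ± 0.25 (SE; adjusted p = 0.0689; 0.0442 with the block), from 4.31 ± 0.56 CPM in crz1 and 13.4 ± 3.98 in crz1cnb1 (SD, n = 3). The high-affinity phosphate transporter gene PHO84 (YML123C, chromosome XIII, 24037 to 25800, overlapping YNCM0001W) had -1.36 ± 0.33, at 257 ± 87.4 and 660 ± 246 CPM. SPL2 (YHR136C, chromosome VIII, 374654 to 375100) had -1.53 ± 0.26 (adjusted p = 0.0442 with the block). PHO12, an acid phosphatase gene with 87.2% of its 50-mers shared, had -0.98 ± 0.24. STE3 had 1.02 ± 0.23 (adjusted p = 0.441; 0.0429 with the block).

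At 0 h edgeR called 1 gene, CNB1, with 73 genes at an unadjusted p under 0.05. These were 1.16% of the tested genes, fewer than the share of 0.05 that would arise without any difference. The replicate block called 5 (CNB1, RDN5-1, STE3, PHO89 and SPL2), the block nested in treatment, added after the data were seen, 21, and DESeq2 7. At an unadjusted p under 0.05 there were 233 genes with the replicate block and 682 with the nested one. Without crz1 control replicate 1, or without crz1cnb1 control replicate 2, edgeR called 2. Other lists called higher in crz1 were pheromone genes (median 0.11; camera adjusted p = 5.80e-05; adjusted p = 0.56 with an estimated correlation) and genes of the opposite mating type (median 0.50; camera adjusted p = 1.16e-04; adjusted p = 0.181 with an estimated correlation). Called lower were ribosomal protein genes (median -0.14; camera adjusted p = 5.15e-16), respiratory chain genes (-0.13; 2.35e-04), cell wall genes (-0.20; 4.80e-04) and Crz1 targets (-0.10; 0.00458). For these 4 lists the adjusted p was 0.474, 0.595, 0.595 and 0.502 with an estimated correlation. Also called lower were M/G1 genes (-0.14; 0.00671; adjusted p = 0.56 with an estimated correlation), osmotic stress genes (-0.16; 0.0233; adjusted p = 0.595 with an estimated correlation) and stationary phase genes (-0.15; 0.0262; adjusted p = 0.568 with an estimated correlation). The calls of osmotic stress and stationary phase genes were lost with the block (adjusted p = 0.0661 and 0.0948), and those of glycolysis and ergosterol genes were gained (medians -0.14 and -0.08, adjusted p = 0.00479 and 0.0425). Adjusted over the list alone, STE3 was higher and 1 Crz1 target lower, and in the other 7 of these lists 0 members passed. Over all genes 0 did in the 9.

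After 48 h in KCl the same difference asked what loss of calcineurin changed in treated cells. SPL2 was lower in crz1, at -2.17 ± 0.30 (SE; 95% interval -2.76 to -1.58; edgeR adjusted p = 0.0147; lower in 3 of 3 pairs), from 0.734 ± 0.25 and 3.30 ± 0.94 CPM (SD, n = 3). Its call was lost without crz1cnb1 KCl replicate 1 (adjusted p = 0.0821), crz1 KCl replicate 1 (0.115) or crz1 KCl replicate 3 (0.133), and ranged from 7.39e-08 to 0.429 over the 26 alternatives. Phosphate starvation genes had a median of -0.14, with 17 of 19 negative (camera adjusted p = 1.49e-10; adjusted p = 0.289 with an estimated correlation). Over all genes 1 was lower, and 4 adjusted over the list alone. PHO84 had -1.57 ± 0.33 and PHO89 -1.01 ± 0.25. CNB1 was higher in crz1 by 6 ± 0.33 (adjusted p = 6.79e-07; 3 of 3 pairs), from 126 ± 9.20 and 1.95 ± 0.80 CPM. RDN5-1, a 5S ribosomal RNA gene chosen after its values were seen, was higher by 2.67 ± 0.34 (adjusted p = 0.00822), with 110 to 163 counts in crz1 and 17 to 26 in crz1cnb1. Its call ended without crz1cnb1 KCl replicate 1, and its adjusted p ranged from 1.34e-13 to 0.199 over the 26 alternatives. At 0 h RDN5-1 had 45 to 87 and 11 to 16 counts. The libraries were of poly(A) RNA, and the treatment of reads with several matches is not given. No share of 50-mers found elsewhere was available for RDN5-1. Whether the difference lies in expression or in the reads assigned to this gene is therefore uncertain.

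In KCl edgeR called 3 genes, 2 higher and 1 lower in crz1, with 70 at an unadjusted p under 0.05, and 1 without crz1cnb1 KCl replicate 1. The 70 genes were 1.11% of those tested, again below a share of 0.05. The block called 4, the block nested in treatment 26, and DESeq2 8. At an unadjusted p under 0.05 there were 183 genes with the replicate block and 430 with the nested one. Pheromone genes were higher in crz1 (median 0.22, 21 of 26 positive; camera adjusted p = 3.70e-09; adjusted p = 0.413 with an estimated correlation). Their member PRM6, which encodes a potassium transporter, had 1.67 ± 0.38. Stationary phase genes were lower (median -0.23; camera adjusted p = 4.40e-05; adjusted p = 0.289 with an estimated correlation), among them GRE1 at -1.18 ± 0.26. Meiosis genes were higher (median 0.09; camera adjusted p = 0.0321; adjusted p = 0.289 with an estimated correlation). Ribosomal protein genes (-0.05; 0.00222), cell wall genes (-0.14; 0.0366), cation transport genes (-0.13; 0.0381) and M/G1 genes (-0.09; 0.0381) were lower, each with an adjusted p = 0.925 with an estimated correlation. Crz1 targets were lower too (-0.11; 0.0381; adjusted p = 0.827 with an estimated correlation). In these 8 lists 0 members were called over all genes. Adjusted over the list alone, 1 pheromone and 1 cell wall gene were higher, and 1 stationary phase gene and 1 Crz1 target lower.

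**Figure D4:**
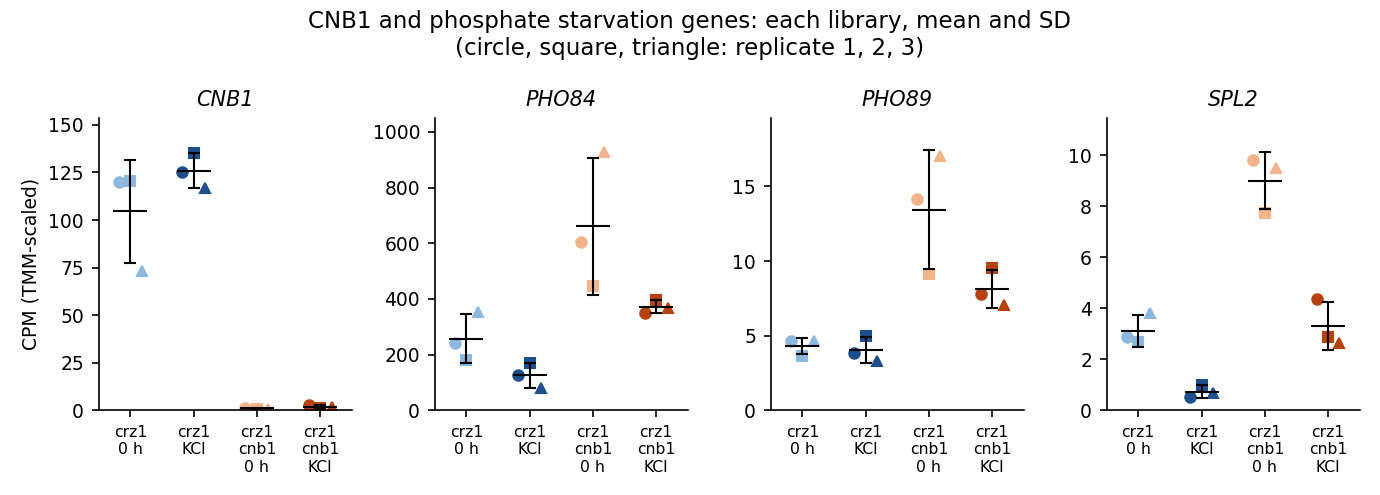
TMM-scaled CPM of CNB1, PHO84, PHO89 and SPL2 in each library (points; circle, square and triangle for replicates 1, 2 and 3), with the mean and SD of the 3 replicates, in the 4 groups. SPL2 lay at 3.11 and 0.734 CPM in crz1 and at 9 and 3.30 CPM in crz1cnb1, at 0 h and in KCl.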

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

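The tests for untreated or 0 h cells in the KCl libraries numbered 2 (over the called genes, over 50 genes and over whole lists) and the fits without the libraries numbered 2 were chosen only after the result was seen.

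Camera found a difference between the KCl responses of the 2 strains for ribosomal protein genes (adjusted p = 1.36e-04; 109 of 132 members above 0), respiratory chain genes (adjusted p = 1.36e-04; 34 of 38 above 0) and iron genes (adjusted p = 0.0229; 20 of 22 below 0). With an estimated correlation the adjusted p was 0.919 for each. Of 208 genes looked at for opposite directions in every pair of the strains, 0 were found.

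The ribosomal protein genes had a median interaction of 0.10, that is, a slightly smaller decrease in crz1 than in crz1cnb1. Of 10000 random lists matched on gene length and expression, 82.0% had a median as large, so a length or expression bias may account for it. The median was above 0 in 2 of 3 replicate numbers (-0.13, 0.34 and 0.10), and largest in number 2. For respiratory chain genes it was -0.08, 0.45 and 0.12, and for iron genes -0.09, -0.60 and 0.04. A dependence on calcineurin stays open and untested apart from these values.

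The KCl libraries numbered 2 lay nearest the controls in both strains. Cells of the 0 h time point under a wrong label are argued against by the sulfate and methionine genes. Their pair 2 medians of -0.65 in crz1 and -0.41 in crz1cnb1 were at least 5.75 times the largest of 6 differences between control libraries (0.0717). That control difference was the smallest of the 32 lists, which raises the ratio. Of 32 lists 2 lay beyond the controls in both strains, the other being M/G1 genes, while iron genes (0.77 and 1.49) did so in crz1cnb1 against a largest control difference of 0.956. Untreated cells kept for 48 h stay open only because no such group was sampled to show what 48 h alone changes: RSB1 had 37.6 and 35.7 CPM in these libraries against 3.92 and 3.70 in the controls numbered 2, while over the genes called in the other strain's pairs 1 and 3 the slopes of pair 2 were 0.197 and 0.302, with 554 of 1128 and 789 of 1245 genes in the same direction. A weaker response of the same genes needed correlations above 0.7, which were not reached. Over those called genes the slopes were at most 0.302 and the correlations 0.315 and 0.463. Over the top 50 the slopes were 0.469 and 0.417 and the correlations 0.637 and 0.648 (43 and 36 in the same direction). The general stress medians of -0.17 and -0.26 were opposite in sign to those of the other pairs. These values argue against a weaker response of the called genes as a whole set. A weaker response of some of them stays open.

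Phosphate starvation genes were lower in crz1 than in crz1cnb1 at both times by camera, a call lost with an estimated correlation (adjusted p = 0.179 at 0 h and 0.289 in KCl), and 0 and 1 of 19 members passed edgeR's test over all genes. Scaling is argued against: the median under another scaling was at least 0.636 of that under TMM. Reads shared between near-identical copies are argued against by the 16 members with unshared sequence, whose median was -0.29 at 0 h and -0.10 in KCl. The list's median was below 0 in 6 of 6 pairs, so the difference was not limited to some replicate numbers. A batch that differed between the strains would give the same signs and cannot be seen this way. Loss of calcineurin is consistent with these values, but with 1 strain per genotype it cannot be told apart from another difference between the strains.

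Other splits of the libraries were counted for each comparison. For the responses and strain differences, 3 libraries against 3 give 10 splits, too few for a share under 0.05. In crz1 the real split gave 36 calls, and 1 of the 10 splits gave as many, with a highest other count of 0. In crz1cnb1 the real split gave 37 calls and the highest other was 0. For the strain differences the real counts were 1 at 0 h and 3 in KCl, and the highest other was 0 in both. For the difference between the responses the real count was 0, so that all 100 of 100 splits had to give as many, which says nothing about chance. The highest other gave 1070 calls, which points to a structure of the samples: 3 of 99 other splits had any call, and 0 did among the 16 others that part every pair of replicate numbers.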

How the results depend on the processing

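The block nested in treatment, the fits without the libraries numbered 2, DESeq2 with the block, list settings other than fry, the block and an estimated correlation, and the strain average were chosen only after the results were seen. The cause was not tested unless stated. No call of a named gene reversed direction. The direction of ribosomal protein and respiratory chain genes in the interaction turned without the libraries numbered 2 (camera adjusted p = 0.44 and 0.971). Calls in crz1 KCl, crz1cnb1 KCl, at 0 h and in KCl between strains (as reported 36, 37, 1 and 3) became 107, 120, 7 and 8 with DESeq2, 304, 314, 5 and 4 with the replicate block, and 576, 616, 16 and 10 with DESeq2 and the block. The KCl responses gave 13 and 6 with glmTreat, which tests against a 1.5-fold change, and 131 and 126 with the block nested in strain. Without the libraries numbered 2 the counts were 61, 29, 1 and 1, and with the block 1630, 1499, 2 and 7. Nested in treatment, the block gave 21 and 26 for the strain differences. At 0 h, library totals gave 2, log2(TPM + 1) gave 4 and log2(TPM + 0.1) gave 2. The interaction gave 0 in every alternative. The correlation of 0.813 was 0.888 above 32 CPM, and 0.643 and 0.388 for single pairs with matched and different numbers. The 28 shared calls were 80 with DESeq2 and 185 with the block. Lists called (15, 15, 3, 10 and 9 for crz1 KCl, crz1cnb1 KCl, interaction, 0 h and in KCl) were 1, 1, 0, 0 and 0 with an estimated correlation and 3, 4, 0, 0 and 0 with fry. The interaction had 6 lists with library totals and 5 with the block nested in treatment, and the strain difference in KCl had 4 without the libraries numbered 2. That fit lost M/G1 (both KCl responses), hexose transport (crz1cnb1 KCl), respiratory chain and stationary phase (0 h), and Crz1 targets, cell wall, cation transport, M/G1 and meiosis (in KCl). It gained heat shock in both KCl responses (adjusted p = 0.0479 and 0.0171, both higher) and meiosis at 0 h (0.0169). The strain average, with 105 calls, gave 7 calls with no replicate block and 17 with the additive replicate block. Library totals also gave 105, but with 72 higher and 33 lower in place of 43 and 62. The count ranged from 13 to 401 without 1 replicate number. Leaving out 1 library gave 12 to 60, 9 to 54, 0 to 0, 1 to 2 and 1 to 4 calls in the order above with the interaction in the middle, 9 to 37 shared calls, a correlation of 0.638 to 0.817, and 11 to 16, 13 to 17, 1 to 9, 4 to 15 and 5 to 16 lists. Library totals shifted the median log2 fold change of all genes to 0.177 (crz1cnb1 KCl) and 0.106 (strain difference at 0 h), and no called list turned under them. They split the calls into 18 higher and 10 lower in crz1 KCl and 23 and 9 in crz1cnb1 KCl. For the named genes over all alternatives, 3817 values stayed on the same side of the threshold, 299 became weaker and 226 stronger; the block made 31 calls stronger and ended none. Of the list calls it ended those of hexose transport (crz1cnb1 KCl), osmotic stress and stationary phase (0 h), added those of ergosterol (interaction and 0 h) and glycolysis (0 h), and changed no other. Depth limits genes near 0.141 CPM, the floor of 3 counts.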

Other observations

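The strain difference averaged over both treatments, with treatment and replicate number as 6 blocks, was a test chosen only after the strain comparisons were seen; the tests of added gene lists were written before their results.

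Averaged over 0 h and KCl, edgeR called 105 genes between the strains, 43 higher and 62 lower in crz1, and 100 had the same sign in 6 of 6 pairs. The fit was blocked on these pairs, so the equal signs follow largely from how the genes were called. With library totals the split turned to 72 higher and 33 lower, and with the additive replicate block 17 genes were called. No set test was run on this average. Of 19 phosphate genes 8 were lower in crz1 over all genes (13 lower and 1 higher adjusted over the list alone), among them PHO84 at -1.49 ± 0.10 (SE; adjusted p = 6.53e-05), SPL2 at -1.86 ± 0.16 (adjusted p = 3.42e-04) and the polyphosphate synthesis genes VTC3 at -0.46 ± 0.04 and VTC4 at -0.26 ± 0.05. PHO5, PHO11 and PHO12, which share sequence, were lower too and are uncertain as single genes. Of 28 cell wall genes 8 were lower (14 lower and 1 higher adjusted over the list alone), such as the mannoprotein genes CWP1 at -0.55 ± 0.06 (adjusted p = 0.0011) and SED1 at -0.40 ± 0.07 and the transglycosylase gene CRH1 at -0.30 ± 0.04, while DAN1 was higher at 1.19 ± 0.20. The transcription factor gene ADR1 had -0.65 ± 0.05 and the zinc transporter gene ZRT1 -0.63 ± 0.05.

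Glucose transporter genes HXT2, HXT4, HXT5 and HXT7 were lower in crz1 (HXT4 at -0.61 ± 0.08, HXT5 at -1.30 ± 0.16; HXT7 shares 95.1% of its 50-mers; adjusted over the list alone, 4 of 14 transporter genes were lower and 2 higher), and the hexokinase gene HXK1 was higher at 0.51 ± 0.07. Of 26 pheromone genes 3 were higher, with 13 higher and 1 lower adjusted over the list alone: FIG1 at 1.29 ± 0.21, PRM6 at 1.45 ± 0.16 and FUS2 at 0.51 ± 0.10. STE3 was higher at 0.82 ± 0.12 (adjusted p = 0.0089). With the strains swapped within blocks, 1 of 32 splits, the real one, gave as many calls, and the highest other gave 5. That is the smallest share these splits can give. The swaps also treated the blocks as independent, though libraries with the same number correlated across treatments (0.309 to 0.582). No conclusion about chance is drawn from these splits. The count was 41, 401 and 13 without replicate number 1, 2 and 3, and 7 with no block. With 1 strain per genotype these values are not tied to CNB1 itself.

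RSB1, PDR5, PDR3 and GRE2 are known targets of the drug resistance factors Pdr1 and Pdr3, so the other targets might rise in KCl too. Over 16 other targets the camera test of limma gave an adjusted p = 0.00111 in crz1 and an adjusted p = 0.0204 in crz1cnb1, adjusted over the 4 tests of added lists, with 13 and 12 above 0 and medians of 0.32 and 0.14. The larger of these was 0.0102 before adjustment, the value for which the limit of 0.05 had been set. With an estimated correlation the adjusted p was 0.454 in both. None was called over all genes in edgeR, and with the replicate block 5 were called in each strain, PDR15, RTA1, YOR1, ICT1 and PDR16. The value of 0.0102 is consistent with the hypothesis, which stays one because its call is lost with an estimated correlation.

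DAN1 rose in KCl in both strains, and HMX1, which is also a member of the iron list, in crz1cnb1. Anaerobic or heme-repressed genes could have risen with them. Over 15 others the camera test of limma gave an adjusted p = 0.125 in crz1 and an adjusted p = 0.731 in crz1cnb1, with 10 and 8 above 0. The hypothesis thus found no support in this test. With the replicate block COX5B and NCE103 were called higher in crz1, and in crz1cnb1 NCE103 was called higher and ERG11 lower.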
